A study of Canis lupus familiaris with 2 samples.

How the data were processed

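Snap-frozen liver tissue with hepatocellular carcinoma from 2 dogs was studied as single nuclei with 10x 3' v3.1 chemistry and sequenced on a NovaSeq instrument, per the labels' protocols, with targets of 5000 nuclei per sample and 40000 reads per nucleus. Each dog gave 1 library, both belong to the same group, and dog 1 and dog 2 are replicates. The deposited matrices hold UMI counts per gene and barcode as integers, written by Cell Ranger 5.0.1 per the file headers, with barcodes already filtered by the authors. The submitters' processing notes name CanFam3.1, Cell Ranger and Seurat 4.2.0. Whether reads in introns were counted and which gene annotation was used are not given in the sources used here. The files hold 30951 genes, of which 12940 carry an identifier without a symbol, and ALB is not found by symbol, so hepatocytes were named without it. The series also describes a comparison with human tumours, which was not analysed here.

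The files hold 10641 barcodes for dog 1, with at least 1084 UMIs and 508 genes each, and 15894 for dog 2, with at least 1746 UMIs and 835 genes. The median mitochondrial share was 0.159% and 0.0995%. Barcodes with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which removed 2 and 4. Doublet scores were computed by simulating doublets in the manner of Scrublet, and the barcodes with the highest scores were removed at 0.8% per 1000 barcodes, 906 (8.52%) in dog 1 and 2020 (12.7%) in dog 2. This left 9733 and 13870 barcodes, with a highest score of 0.683 in dog 1 and 0.667 in dog 2. Median scores of the low-UMI clusters named below were 0.058 and 0.079. Those of the named classes other than hepatocyte-like lay between 0.429 and 0.587, so the removed barcodes may include single nuclei of these classes. Each dog was clustered separately on 3000 variable genes, 30 principal components and 20 neighbours with the Leiden method at resolution 1.0 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9; figures with matplotlib 3.10.9). Members of the gene lists were left out of the clustering features.

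Clusters were named from marker genes of 16 classes. A cluster took the name of the class other than hepatocyte with the most markers among its 60 top genes by fold over the other clusters, if there were at least 3. The remaining clusters were called hepatocyte-like if at least 3 hepatocyte markers stood at 10 CPM or more and 2-fold above the classes named so far. CPM are counts scaled to a common library total. The rule for hepatocyte-like clusters and the limit below which an unnamed cluster counted as low in UMIs, a median of 1.25 times the lowest barcode total with fewer than 3 hepatocyte markers among the top genes, were set after the data had been seen. Classes were called hepatocyte-like and so on because the labels give no cell types. The labels do not separate tumour from other parenchyma. The markers, the 24 gene lists (623 entries, 556 found in the files), the 76 ligand and receptor pairs, the filters, the tests and the alternatives given for them were chosen before the data were examined. Alternatives with barcodes of at least 1.5 times the lowest UMI total, with low-UMI clusters counted as hepatocyte-like and with the free-RNA background subtracted were chosen afterwards.

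Classes with at least 20 nuclei in each dog were compared by summing counts per dog and class into 10 libraries of 5 classes. A class was set against the mean of the other classes with the dog as block, so each comparison is within animals. Each class is also part of the mean for the others, so the comparisons of the 5 classes are not independent. A list far higher in 1 class tends to be lower in the others. The edgeR quasi-likelihood test was used with TMM factors and filterByExpr (edgeR 4.0.16, R 4.3.3), which kept 11128 genes with a biological coefficient of variation of 0.258, and p values were adjusted by Benjamini-Hochberg over all genes at 0.05 and also over the list genes alone. With 2 dogs, all classes shared a single estimate of the spread, on 4 residual degrees of freedom. Gene lists were tested with camera on log-CPM (limma 3.58.1) at a preset correlation of 0.01, beside an estimated correlation and fry. DESeq2 1.42.0 was run as an alternative test. For every list and class at most 3 higher and 2 lower members with the largest change and the same sign in both dogs were chosen for naming, and a part of these is named. Values per gene are log2 fold changes with their standard error.

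Shares of nuclei carry exact binomial intervals. Cycling nuclei were counted from 22 proliferation core genes after thinning to 1000 UMIs. Dog 2 was set against dog 1 within classes of at least 100 nuclei without a test, for genes with at least 100 CPM in either dog. For this, the 12 genes with the largest differences in each direction were listed for hepatocyte-like nuclei and 4 for the other classes, with exact Poisson intervals that cover counting error only, and some of the listed genes are not reported here. List medians were set against 10000 random lists matched on expression, for lists with at least 5 members at 5 CPM. A prior of 0.5 counts was added in ratios. The free-RNA background was taken as the profile of the low-UMI cluster of the same dog, scaled to the lowest hepatocyte marker level among the other 4 classes of the fit, 973.3 UMIs per droplet in dog 1 and 1782 in dog 2, and subtracted from the summed counts. Hepatocyte-like clusters were compared over genes of at least 20 CPM.

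The tests were tested on simulated data built from these libraries. Genes were raised or lowered, and calls in the right direction were counted. Of genes changed 2-fold, 23 of 67 (34.3%) were called in hepatocyte-like and 14 of 66 (21.2%) in T and NK-like nuclei. Of genes changed 4-fold, 61 of 65 (93.8%) and 50 of 65 (76.9%) were called. Of unchanged genes 1 of 10573 and 4 of 10586 were called. A list of 20 raised genes was called by camera in both classes, and 0 of 20 and 1 of 20 unchanged lists were. Simulated genes were drawn independently of each other. In the data the estimated correlation reached 0.806 for the proliferation core in hepatocyte-like nuclei. The simulation therefore does not check the camera calls for lists of correlated genes. Apart from the raised or lowered genes, no simulated gene differed between classes. In the data 2197 of 11128 genes were called higher and 1847 lower in hepatocyte-like nuclei. The simulated rates of calls may therefore not carry over to the data. Gene neighbourhood was taken from a RefSeq gene table of the assembly UU_Cfam_GSD_1.0, to which 14898 of 16036 symbols of the files matched, and was used for gene order only. Bootstrap intervals of a list's or block's median were taken by drawing its genes with replacement, so they cover the spread between genes and not between dogs.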

Results

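Nuclei from snap-frozen liver tissue of 2 dogs with hepatocellular carcinoma (HCC), a malignant tumour of hepatocytes, were profiled by droplet 3' RNA sequencing, in which each captured transcript carries a unique molecular identifier (UMI). Both dogs belonged to the same group and gave 1 library each, so dog 1 and dog 2 were its replicates. The labels gave a target of 5000 nuclei per sample. The deposited matrices held 10641 barcodes and 39621076 UMIs for dog 1, and 15894 barcodes and 72344732 UMIs for dog 2. After filtering and removal of the barcodes with the highest doublet scores, 9733 barcodes of dog 1 had a median of 1435 UMIs and 888 genes. The 13870 barcodes left in dog 2 had a median of 3077 UMIs and 1724 genes. The series asked which cell types make up canine HCC, how they may communicate, and how stemness and the cell cycle are distributed among them. The labels did not separate tumour from non-tumour parenchyma, so hepatocyte-like nuclei were not divided by tissue part.

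Hepatocyte-like nuclei, with APOB, TF, ASGR2 and ITIH1 among their markers, were the most numerous class in both dogs. They made up 68.6% of the named nuclei in dog 1 (95% exact binomial interval 67.3% to 69.9%) and 72.9% in dog 2 (72.0% to 73.8%), a mean of 70.8% ± 3.07 (SD, n = 2). Endothelial-like nuclei, with PTPRB, EGFL7 and STAB2, made up 5.12% (4.53% to 5.77%) and 11.8% (11.2% to 12.4%). Mesenchymal-like nuclei, with COL3A1, PTH1R, CCBE1 and ACTA2, made up 3.88% (3.36% to 4.45%) and 5.53% (5.10% to 5.98%). Macrophage-like nuclei, with CD163, MARCO, MSR1 and VSIG4, made up 7.56% (6.84% to 8.32%) and 5.73% (5.29% to 6.19%). T and NK-like nuclei, with CD2, CD96, THEMIS and BCL11B, made up 14.9% in dog 1 (13.9% to 15.9%) and 2.64% in dog 2 (2.34% to 2.97%). These shares differed most between the dogs. The means over the dogs were 8.45% ± 4.70 for endothelial-like, 4.70% ± 1.17 for mesenchymal-like, 6.64% ± 1.29 for macrophage-like and 8.75% ± 8.65 for T and NK-like nuclei (SD, n = 2). A dendritic-like cluster of 148 nuclei, with CLNK, WDFY4 and CIITA, was named in dog 2, where it made up 1.42% (1.20% to 1.67%). NLRP1 and ARHGAP22 were among its leading genes. With WDFY4 they were also among those of the largest macrophage-like cluster of dog 1, of 351 nuclei. Similar nuclei may thus carry different class names in the 2 dogs, which also bears on the macrophage-like class. Intervals cover counting error only.

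In each dog a large cluster with a median near the lowest barcode total, 1189 UMIs against a lowest total of 1084 in dog 1 and 1904 against 1746 in dog 2, had fewer than 3 markers of any class and stayed unnamed. It held 4756 droplets (48.9% of those analysed) in dog 1 and 3421 (24.7%) in dog 2. Hepatocyte marker transcripts occurred in every class: endothelial-like, mesenchymal-like, macrophage-like, T and NK-like and dendritic-like droplets carried 0.787 to 1.05 times as many hepatocyte marker UMIs per droplet as these low-UMI clusters. The free-RNA background estimated from these clusters came to 14.6% of the UMIs of hepatocyte-like nuclei in dog 1 and 32.4% in dog 2. In endothelial-like, mesenchymal-like, macrophage-like and T and NK-like nuclei it came to 30.8%, 28.4%, 29.4% and 61.5% in dog 1, and to 49.96%, 59.95%, 61.2% and 78.9% in dog 2. Levels and folds below include it unless its subtraction is named. A further cluster of 29 droplets in dog 2 also stayed unnamed. With the low-UMI clusters counted as hepatocyte-like, the mean shares were 4.80% for T and NK-like, 4.09% for macrophage-like and 3.07% for mesenchymal-like nuclei. With barcodes of at least 1.5 times the lowest UMI total, T and NK-like nuclei stood at 3.38%.

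**Figure D1:**
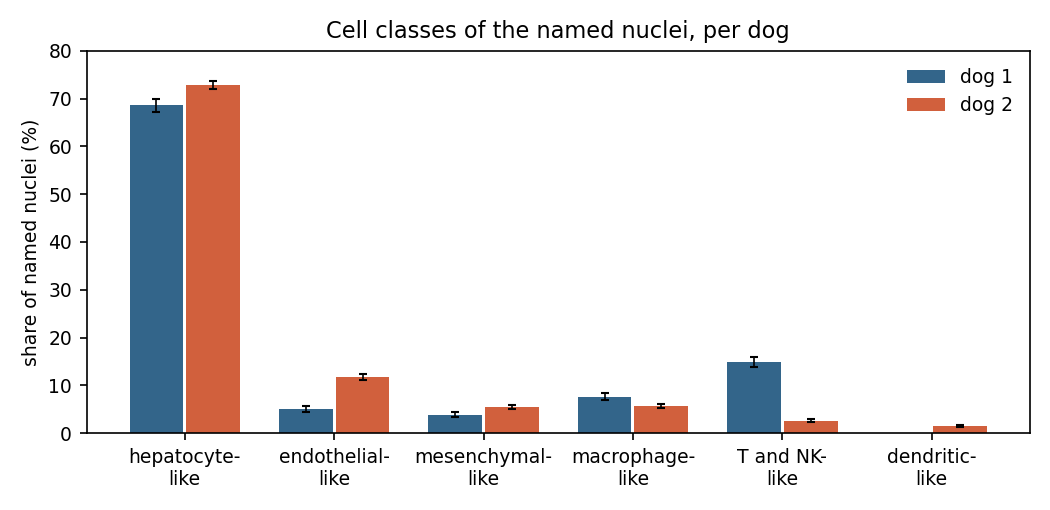
Share of named nuclei in each cell class (percent, vertical axis starting at 0) for dog 1 and dog 2, with 95% exact binomial intervals as error bars. Hepatocyte-like nuclei made up 68.6% and 72.9%, and T and NK-like nuclei 14.9% in dog 1 and 2.64% in dog 2.

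Gene programmes of each class were then compared with the mean of the other classes within each dog, on counts summed per dog and class. Hepatocyte-like nuclei carried the metabolic programmes of the liver. Of the lipid synthesis and uptake list, 20 of 24 tested genes were higher (22 adjusted over the list alone), as were 15 of 16 fatty acid oxidation genes (16 adjusted over the list alone). So were 12 of 12 urea cycle and gluconeogenesis genes (12), 11 of 12 bile acid synthesis and transport genes (12), 13 of 13 drug metabolism genes (13) and 11 of 12 acute phase and complement genes (12). No tested member of these lists was lower, also by DESeq2 and at an unadjusted p under 0.05 (0 genes in each list by edgeR). FASN, the fatty acid synthase, was higher by 2.91 ± 0.25 (log2, SE) and MLXIPL, a carbohydrate-responsive activator of lipogenic genes, by 2.12 ± 0.17. PPARA, the nuclear receptor that drives fatty acid oxidation, was higher by 1.92 ± 0.21, and NAGS, which makes the activator of carbamoyl phosphate synthetase, by 2.19 ± 0.18. ABCB4, the canalicular phospholipid transporter, was higher by 2.65 ± 0.26, the cytochrome P450 gene CYP3A12 by 1.96 ± 0.23 and the complement gene C5 by 1.97 ± 0.21. The medians of the lists lay between 1.15 and 1.45 (log2), with camera adjusted p values, by Benjamini-Hochberg, between 5.05e-08 and 3.84e-05 (adjusted p = 0.692 with an estimated correlation for each).

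Targets of Wnt and beta-catenin signalling were also higher in hepatocyte-like nuclei, with 12 of 15 tested genes called (13 adjusted over the list alone) and a median of 1.41. The list's camera adjusted p was 3.84e-05 by Benjamini-Hochberg (adjusted p = 0.692 with an estimated correlation). NOTUM, a secreted enzyme that inactivates Wnt proteins, was higher by 2.86 ± 0.40, the ammonium transporter gene RHBG by 2.50 ± 0.30 and the T-box factor TBX3 by 2.17 ± 0.27. The stem and progenitor list went both ways, with 6 of 20 genes higher and 3 lower (6 and 3 adjusted over the list alone). LGR5, a receptor for R-spondins, was higher by 1.97 ± 0.22, while NOTCH1 was lower, at −4.54 ± 0.49, and so was the hyaluronan receptor gene CD44. Fetal liver and HCC marker genes did not pass the test, with 0.41 ± 0.19 for AFP and 0.55 ± 0.24 for GPC3. AFP reached 21810 normalised CPM (counts scaled to a common library total) in dog 1 and 11370 in dog 2 in hepatocyte-like nuclei, against 16080 and 9020 on average in the other classes, where the free-RNA background is included. With it subtracted both genes were called higher in hepatocyte-like nuclei by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, AFP by 2.91 ± 0.38 (adjusted p = 0.0130) and GPC3 by 3.56 ± 0.80 (adjusted p = 0.0307). By the same test GPC3 was then also called higher in mesenchymal-like nuclei, by 3.99 ± 0.80 (adjusted p = 0.0418). T and NK-like nuclei had 0 counts of GPC3 left in either dog. The list's median was 0.40, its mean −0.18 and its camera adjusted p 0.516 by Benjamini-Hochberg.

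Among signalling genes, hepatocyte-like nuclei were the class with more VEGFA, which encodes the vascular endothelial growth factor A, by 2.17 ± 0.17. It was the single higher gene of 23 angiogenic ligands and receptors (1 adjusted over the list alone). Of these 10 were lower (14), among them the receptor NRP2 at −3.41 ± 0.51. The activin subunit genes INHBA (2.71 ± 0.30) and INHBE (2.43 ± 0.46) were among 9 of 27 growth factor ligands that were higher (9 adjusted over the list alone). As many were lower, 9 (10), with TGFB1 at −3.59 ± 0.38. ERBB3, a neuregulin receptor (2.46 ± 0.18), and FGFR3 (1.91 ± 0.22) were among 9 of 28 growth factor receptors that were higher (9). A further 10 were lower (10), with AXL at −3.31 ± 0.56. The interleukin receptor genes IL1R1 (1.90 ± 0.20) and IL6R (1.15 ± 0.18) were the 2 higher of 17 chemokine and cytokine receptors, and 5 were lower (2 and 9).

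Immune and matrix lists were lower in hepatocyte-like nuclei. Of 34 matrix and remodelling genes 21 were lower and 1, FN1, which encodes fibronectin, was higher, by 1.30 ± 0.16 (24 and 1 adjusted over the list alone). Of 11 antigen presentation genes 8 were lower (10 adjusted over the list alone), among them the class I gene DLA-79 at −2.26 ± 0.35. Of 15 chemokines and cytokines 6 were lower and of 19 immune checkpoint genes 8 (7 and 8 adjusted over the list alone). The medians were −2.39 for matrix, −1.86 for angiogenic, −1.70 for chemokine and cytokine, −1.44 for checkpoint, −1.39 for antigen presentation and −1.06 for chemokine receptor genes. Camera adjusted p values, by Benjamini-Hochberg, lay between 3.92e-06 and 0.0236 for these lists (adjusted p = 0.692 with an estimated correlation for each). Vimentin, VIM, was lower at −3.31 ± 0.41 and the hexokinase gene HK1 at −4.01 ± 0.53.

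The remaining lists had no camera call in hepatocyte-like nuclei. They were epithelial-mesenchymal genes (7 of 13 higher and 3 lower, 7 and 3 adjusted over the list alone) and hypoxia and glycolysis (4 of 16 higher and 4 lower, 4 and 4). The others were interferon response (2 of 16 higher and 4 lower, 2 and 4), p53 and DNA damage (6 of 18 higher and 2 lower, 6 and 3), and dissociation and early response (1 of 14 higher, 1). Their examples were BNIP3, a mitophagy gene induced by hypoxia (1.58 ± 0.29), the interferon signalling gene STAT2 (1.26 ± 0.20), the growth arrest gene GADD45A (1.74 ± 0.24) and the co-chaperone gene BAG3 (3.05 ± 0.26). Of 24 S phase genes 1 was higher, CCNE2, a cyclin of the entry into S phase (1.81 ± 0.32), and 3 were lower (1 and 1 adjusted over the list alone). Of 32 G2 and M phase genes 4 were lower (0 adjusted over the list alone). None of 17 proliferation core genes passed by edgeR, 1 was lower at an unadjusted p under 0.05 and 1 was lower by DESeq2. Of the genes chosen for naming 69 could be tested with the background subtracted, and 53 were still called. A log2 fold more than 1.5 times as large was found for 51, with a median size over the 69 of 5.20 against 2.17 and a median SE of 1.03 against 0.29. LGR5 then stood at 8.31 ± 1.89, TBX3 at 10.32 ± 0.94, IL1R1 at 9.999 ± 2.03, INHBA at 8.73 ± 1.66 and VEGFA at 4.25 ± 0.62. For 56 of the 69 a library had 0 counts left, so such folds depend on the prior count. The genes named as called in hepatocyte-like nuclei were picked for the same sign in both dogs, so that agreement is not a separate result. Their edgeR quasi-likelihood adjusted p values, by Benjamini-Hochberg, lay between 0.000349 and 0.00466. Over 11128 genes 2197 were higher and 1847 lower. Of 432 tested list genes 139 were higher and 100 lower (145 and 115 adjusted over the list genes alone). With DESeq2's size factors the median of all genes moved by −0.10. With the free-RNA background subtracted it moved by 0.25, and 129 list genes were higher and 33 lower, 79.6% against 58.2% of the calls. Against the summed other nuclei 129 were higher and 161 lower (44.5% higher).

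Endothelial-like nuclei carried the angiogenic receptors. Of 23 angiogenic ligands and receptors 14 were higher and 1 lower (15 and 2 adjusted over the list alone), led by the Notch ligand gene DLL4 (6.03 ± 0.40) and the vascular endothelial growth factor receptor genes KDR (5.98 ± 0.42) and FLT4 (5.92 ± 0.43). NOTCH1 (4.09 ± 0.32) and PROM1, which encodes CD133 (3.83 ± 0.53), were among 4 of 20 stem and progenitor genes that were higher, with 1 lower (4 and 2 adjusted over the list alone). WNT2, a Wnt ligand (4.53 ± 0.47), and GAS6, a ligand of AXL and MERTK (4.13 ± 0.62), were among 9 of 27 growth factor ligands that were higher (10). IGF1R (3.48 ± 0.39) and TGFBR2 (2.87 ± 0.28) were among 8 of 28 growth factor receptors, with 3 lower (8 and 9). Matrix genes were higher for 10 of 34 (15 higher and 4 lower adjusted over the list alone), with ADAMTS9, a matrix protease gene (4.34 ± 0.47), and ITGA5, a fibronectin receptor subunit gene (3.77 ± 0.37).

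The immune receptor genes OSMR, the oncostatin M receptor (4.15 ± 0.48), and LIFR (2.07 ± 0.32) were among 4 of 17 chemokine and cytokine receptors that were higher in endothelial-like nuclei (4 higher and 5 lower adjusted over the list alone). Further calls were 3 higher and 1 lower of 15 chemokines and cytokines (3 and 2), with CXCL16 at 3.70 ± 0.52. Of 19 checkpoint genes 4 were higher and 2 lower (7 and 3), with PDCD1LG2, which encodes PD-L2, at 2.73 ± 0.43. Of 13 epithelial-mesenchymal genes 3 were higher (4 and 1), with the cadherin gene CDH11 at 4.41 ± 0.55 and the tight junction gene TJP1 at 2.06 ± 0.18. Of 16 hypoxia and glycolysis genes 2 were higher and 1 lower (3 and 1), with HIF1A at 1.23 ± 0.18 and the glycolytic regulator gene PFKFB3 at −1.61 ± 0.22. Single calls stood in the S phase (1 higher, 0 adjusted over the list alone), G2 and M phase (1 higher and 1 lower, 0 and 0), interferon (1 and 1, 1 and 1) and p53 lists (2 and 1, 4 and 3). Lower genes stood in the lipid (1 lower, 0), urea cycle (1 lower, 5) and drug metabolism lists (1 lower, 1). Proliferation core, Wnt, fatty acid oxidation, bile acid, acute phase, antigen presentation and dissociation lists held no edgeR call. At an unadjusted p under 0.05 they held 2, 8, 6, 7, 6, 4 and 0 lower genes, and 1 higher gene each for antigen presentation and dissociation. By DESeq2 they held 1 lower gene each for Wnt, fatty acid oxidation and bile acid and 0 for the others.

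As lists, angiogenic genes (median 3.47, camera adjusted p = 3.02e-07), matrix genes (1.16, 0.00618) and growth factor ligands (0.51, 0.0260) were higher in endothelial-like nuclei by camera with Benjamini-Hochberg adjustment, each with adjusted p = 0.692 with an estimated correlation. Wnt targets and the 6 metabolic and acute phase lists were lower, with medians between −0.66 and −0.46 and camera adjusted p values between 3.85e-05 and 0.0125 (adjusted p = 0.692 with an estimated correlation for each). Hepatocyte-like nuclei, where these lists were higher, were part of the mean compared with, so these calls partly restate that result. The named endothelial genes were picked for the same sign in both dogs. Their edgeR quasi-likelihood adjusted p values, by Benjamini-Hochberg, lay between 0.000132 and 0.00414. Over the 45 chosen genes that could be tested with the background subtracted the median size of the log2 fold was 2.21, and 3.88 after subtraction, where 21 were still called. Of all genes 1032 were higher and 253 lower, and of list genes 66 were higher and 15 lower (73 and 38 adjusted over the list genes alone). With the free-RNA background subtracted, which moved the median of all genes by 0.22, 46 list genes were higher and 2 lower (95.8% against 81.5% higher). Against the summed other nuclei 105 were higher and 141 lower (42.7% higher).

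Mesenchymal-like nuclei carried the matrix programme. Of 34 matrix and remodelling genes 26 were higher and none lower by edgeR, DESeq2 or an unadjusted p under 0.05 (29 and 0 adjusted over the list alone), led by the collagen gene COL5A1 (6.97 ± 0.44), THBS2, which encodes thrombospondin 2 (6.29 ± 0.51), and the periostin gene POSTN (6.05 ± 0.26). Of the angiogenic list 6 were higher (7), with the angiopoietin genes ANGPT4 (7.94 ± 0.65) and ANGPT1 (5.19 ± 0.39) and the lymphatic growth factor gene VEGFD (4.96 ± 0.32). Hepatocyte growth factor, HGF (4.71 ± 0.37), TGFB3 (5.55 ± 0.64) and PDGFD (4.25 ± 0.46) were among 7 of 27 growth factor ligands that were higher (11 and 1 lower). PDGFRB (5.18 ± 0.23) was among 7 of 28 receptors (8 and 1 lower). TGFB3 stood at 401.6 normalised CPM in dog 1 and 11.3 in dog 2.

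Early response genes were higher in mesenchymal-like nuclei for 3 of 14 (3 adjusted over the list alone), with EGR1 at 3.91 ± 0.62 and FOS at 3.06 ± 0.64. FOS stood at 89.3 normalised CPM in dog 1 and 2.26 in dog 2. After subtraction of the free-RNA background the folds were 6.08 ± 1.47 for EGR1 and 4.71 ± 1.02 for FOS (log2, SE), and both calls ended. For EGR1 the spread grew by more than the fold. For FOS fold and spread grew nearly alike, so the spread alone does not account for its lost call. Antigen presentation genes were lower for 4 of 11 (5). So were chemokines and cytokines for 3 of 15 (5), with the T and NK cell growth factor gene IL15 at −2.06 ± 0.36. With the same subtraction IL15 stood at −4.34 ± 1.09, and its call ended, with a spread that grew by more than the fold, as for EGR1. Further calls were 2 of 20 stem and progenitor genes higher (3), 2 higher and 1 lower of 17 chemokine and cytokine receptors (2 and 3), among the higher ones OSMR, and 1 of 19 checkpoint genes higher (1). Of 13 epithelial-mesenchymal genes 2 were higher (2 and 1 lower), and of 16 hypoxia genes 1, adrenomedullin, ADM, by 2.53 ± 0.50 (1). Of 12 bile acid genes 1 was higher (1 and 4 lower) and of 18 p53 genes 2 (2), with the death receptor gene FAS at 1.53 ± 0.20, while 1 of 32 G2 and M phase genes was lower (0). S phase, proliferation core, Wnt, lipid, fatty acid oxidation, urea cycle, drug metabolism, acute phase and interferon lists held no edgeR call. At an unadjusted p under 0.05 they held 0, 0, 7, 11, 3, 5, 7, 4 and 2 lower genes, with 1 higher for S phase and 2 for interferon, and DESeq2 called 1 higher interferon gene and none in the others.

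As lists, matrix (median 3.95, camera adjusted p = 3.10e-20), dissociation and early response (0.84, 0.0224), growth factor ligands (0.57, 0.0371) and growth factor receptors (0.10, 0.0101) were higher by camera with Benjamini-Hochberg adjustment (adjusted p = 0.692 with an estimated correlation for each). So were angiogenic genes by camera with the same adjustment (0.85, 0.0468, adjusted p = 0.748 with an estimated correlation). Antigen presentation (−0.97, 0.000703), chemokines and cytokines (−1.08, 0.00950), Wnt targets and the 6 metabolic and acute phase lists were lower, each with adjusted p = 0.692 with an estimated correlation by camera with Benjamini-Hochberg adjustment. The last 7 had camera adjusted p values, by Benjamini-Hochberg, between 2.41e-05 and 0.0443. They were higher in hepatocyte-like nuclei, which were part of the mean compared with, so these calls partly restate that result. The named mesenchymal genes were picked for the same sign in both dogs. Their edgeR quasi-likelihood adjusted p values, by Benjamini-Hochberg, lay between 2.40e-05 and 0.0165. Over the 32 chosen genes the median size was 2.61 (log2), and 5.39 with the background subtracted, where 18 were still called. Of all genes 1114 were higher and 210 lower, and of list genes 60 were higher and 9 lower (65 and 11 adjusted over the list genes alone). Against the summed other nuclei 70 list genes were higher and 60 lower (53.8% against 87.0% higher), and the background subtraction moved the median of all genes by 0.14.

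Macrophage-like nuclei carried chemokine, checkpoint and antigen presentation genes. Of 15 chemokines and cytokines 11 were higher (12 adjusted over the list alone), with interleukin 10, IL10 (6.70 ± 0.62), and tumour necrosis factor, TNF (5.82 ± 0.67). CD86, a ligand of CD28 and CTLA4 (5.15 ± 0.34), and PDCD1LG2 (3.22 ± 0.44) were among 7 of 19 checkpoint genes that were higher (8 and 1 lower). The class II genes DLA-DQA1 (3.68 ± 0.33) and DLA-DRA and their chaperone CD74 (3.60 ± 0.28) were among 6 of 11 antigen presentation genes that were higher (8 and 1 lower). CSF1R, the receptor of macrophage colony-stimulating factor, was higher by 5.65 ± 0.27. With it AXL (3.12 ± 0.43) and MERTK (1.75 ± 0.33), receptors for the clearance of dying cells, were among 4 of 28 growth factor receptors, of which 5 were lower (4 and 9). AXL had its highest level in mesenchymal-like nuclei in both dogs, however. It stood there at 28.8 CPM in dog 1 and 26.3 in dog 2, against 19.3 and 21.9 in the next class.

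Of 32 G2 and M phase genes 5 were higher in macrophage-like nuclei (7 adjusted over the list alone), with the cytokinesis gene GAS2L3 at 3.82 ± 0.57. Of 17 proliferation core genes 2 were (10 adjusted over the list alone), with HMMR, a spindle gene, at 1.40 ± 0.22. It stood at 1.58 ± 0.37 with the free-RNA background subtracted, and its call ended because the spread grew by more than the fold. None of 24 S phase genes was called by edgeR or DESeq2, and 2 were higher at an unadjusted p under 0.05. Other calls were 6 of 17 chemokine and cytokine receptors higher and 4 lower (7 and 5), with TNFRSF1B at 4.97 ± 0.55, and 6 of 16 interferon genes higher (7), with SAMD9L at 1.61 ± 0.20. Of 34 matrix genes 2 were higher and 6 lower (3 and 12), with the protease gene MMP14 at 2.09 ± 0.26 and the basement membrane gene COL4A1 at −3.04 ± 0.49. There were 2 higher and 3 lower of 23 angiogenic genes (2 and 3), with NRP2 at 3.37 ± 0.36, and 2 higher and 3 lower of 27 growth factor ligands (2 and 3), with PDGFC at 3.80 ± 0.27. Of 16 hypoxia and glycolysis genes 3 were higher (3 and 2 lower), with PFKFB3 at 2.20 ± 0.17. Of 20 stem and progenitor genes 1, CD44 (2.87 ± 0.37), was higher and 1 lower (1 and 1), and of 13 epithelial-mesenchymal genes 2 were higher and 2 lower (2 and 2). The Wnt (1 higher, 1), lipid (1 higher, 1), fatty acid oxidation (1 lower, 0), bile acid (1 and 1, 1 and 3), dissociation (1 and 1, 1 and 1) and p53 lists (1 higher, 1) held single calls. Urea cycle, drug metabolism and acute phase lists held none by edgeR, with 5, 5 and 6 lower genes at an unadjusted p under 0.05 and 2, 1 and 1 by DESeq2.

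As lists, chemokines and cytokines (median 2.65, camera adjusted p = 1.55e-07), antigen presentation (0.98, 2.18e-05), checkpoints (1.47, 0.00289), G2 and M phase (0.65, 0.00289) and interferon response (0.08, 0.0443) were higher by camera with Benjamini-Hochberg adjustment (adjusted p = 0.692 with an estimated correlation for each). So was the proliferation core by camera with the same adjustment (1.44, 0.00622, adjusted p = 0.707 with an estimated correlation). Matrix (−1.63, 0.00911), Wnt targets and the 6 metabolic and acute phase lists were lower, each with adjusted p = 0.692 with an estimated correlation by camera with Benjamini-Hochberg adjustment. The last 7 had camera adjusted p values, by Benjamini-Hochberg, between 0.00142 and 0.0162. They were higher in hepatocyte-like nuclei, which were part of the mean compared with, so these calls partly restate that result. The named macrophage genes were picked for the same sign in both dogs. Their edgeR quasi-likelihood adjusted p values, by Benjamini-Hochberg, lay between 7.96e-06 and 0.0111. Over 55 chosen genes the median size was 2.20 (log2), and 4.43 with the background subtracted, where 28 were still called. Of all genes 1130 were higher and 333 lower, and of list genes 63 were higher and 27 lower (71 and 47 adjusted over the list genes alone). With the free-RNA background subtracted 34 list genes were higher and 7 lower (82.9% against 70.0% higher), and against the summed other nuclei 70 were higher and 47 lower (59.8%).

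T and NK-like nuclei carried lymphocyte receptors. The interleukin 2 receptor genes IL2RB (6.81 ± 0.44) and IL2RA (4.92 ± 0.55) and the interleukin 18 receptor gene IL18R1 (5.30 ± 0.50) were among 4 of 17 chemokine and cytokine receptors that were higher (4 and 1 lower adjusted over the list alone). Of 19 checkpoint genes 4 were higher (5), with the costimulatory genes ICOS (5.44 ± 0.54) and CD226 (5.14 ± 0.43) and the CD28 ligand gene CD80 (4.29 ± 0.27). The chemokine gene CCL5 was higher by 4.12 ± 0.29 and was among 3 of 15 chemokines and cytokines (4 and 1 lower). Class I genes and their activator rose above the other classes, with NLRC5 at 2.35 ± 0.19, DLA-12 at 2.12 ± 0.18 and DLA-79 among 5 of 11 antigen presentation genes (10 adjusted over the list alone). Reads of the near-identical canine class I and class II genes may be divided between copies, so single DLA values are uncertain.

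Further calls in T and NK-like nuclei were 1 higher and 1 lower of 15 Wnt targets (1 and 1 adjusted over the list alone), with the T cell transcription factor gene LEF1 at 4.21 ± 0.60. Of the others, 1 of 20 stem and progenitor genes was higher (2), as was 1 of 27 growth factor ligands (1), and 1 of 28 growth factor receptors was higher and 1 lower (1 and 1). Matrix genes were lower for 2 of 34 (2), with the integrin gene ITGAV at −1.08 ± 0.21. The S phase, G2 and M phase, proliferation core, angiogenic, epithelial-mesenchymal, hypoxia, lipid, fatty acid oxidation, urea cycle, bile acid, drug metabolism, acute phase, interferon, dissociation and p53 lists held no edgeR call. Of these, DESeq2 called 1 higher G2 and M phase gene, 3 lower angiogenic genes, 1 higher and 2 lower interferon genes (as many adjusted over the list alone by edgeR), 1 lower dissociation gene and 1 higher p53 gene. At an unadjusted p under 0.05 they held between 0 and 4 higher and between 0 and 5 lower genes each.

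As lists, antigen presentation (median 1.10, camera adjusted p = 1.19e-09), chemokine and cytokine receptors (0.16, 0.00917) and G2 and M phase (0.14, 0.0232) were higher in T and NK-like nuclei by camera with Benjamini-Hochberg adjustment (adjusted p = 0.692 with an estimated correlation for each). Matrix (−1.31, 0.000668), angiogenic (−1.36, 0.00622), dissociation (−0.56, 0.0406) and growth factor receptor genes (−0.59, 0.0408) were lower by camera with the same adjustment (adjusted p = 0.692 with an estimated correlation for each). Checkpoint genes were called higher by camera (adjusted p = 0.0396 by Benjamini-Hochberg, and adjusted p = 0.692 with an estimated correlation), with a median of −0.31 and a mean of 0.42. The named T and NK genes were picked for the same sign in both dogs. Their edgeR quasi-likelihood adjusted p values, by Benjamini-Hochberg, lay between 4.87e-05 and 0.0225. Over the 20 chosen genes the median size was 2.79 (log2), and 5.59 with the background subtracted, where 19 were still called. Of all genes 460 were higher and 156 lower, and of list genes 20 were higher and 4 lower (22 and 5 adjusted over the list genes alone). With DESeq2 26 list genes were higher and 18 lower (59.1% against 83.3% higher). With the background subtracted, which moved the median of all genes by −0.26, there were 25 and 11 (69.4%), and against the summed other nuclei 58 and 102 (36.3%). Camera called 59 of 120 list and class tests in all, and none of these with an estimated correlation, where 5 of the 120 had an unadjusted p under 0.05. Of the 120 tests fry called 23, and 22 of these were among the 59.

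**Figure D2:**
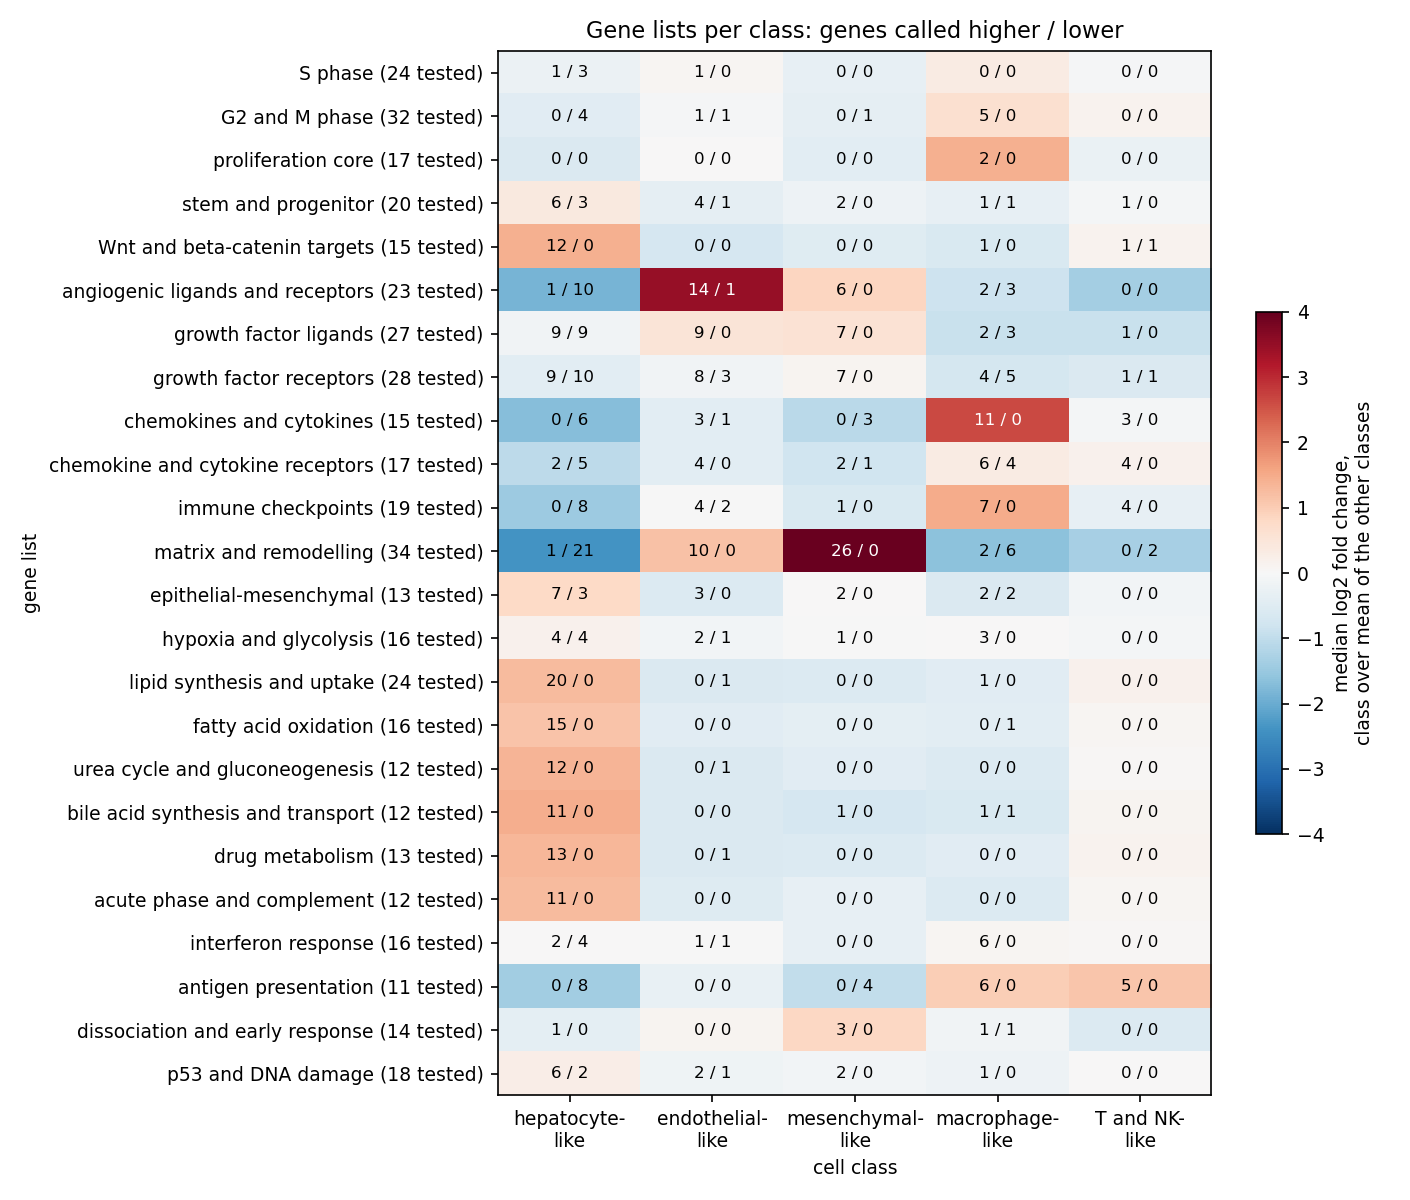
Median log2 fold change of the tested genes of 24 lists (vertical axis) in 5 cell classes (horizontal axis) against the mean of the other classes, as colour, with the numbers of genes called higher and lower written in each field. Matrix genes were higher in mesenchymal-like nuclei (26 of 34), angiogenic genes in endothelial-like nuclei (14 of 23) and the metabolic lists in hepatocyte-like nuclei.

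Cycling nuclei were counted in each class as those with UMIs of at least 2 distinct proliferation core genes, such as MKI67, TOP2A and CENPF, after thinning every nucleus to 1000 UMIs. Macrophage-like nuclei held the highest mean share, 5.05% in dog 1 (95% exact binomial interval 3.07% to 7.78%, median depth 3045 UMIs) and 6.37% in dog 2 (4.54% to 8.63%, 2725 UMIs), 5.71% ± 0.928 (SD, n = 2). Hepatocyte-like nuclei differed between the dogs, with 0.498% in dog 1 (0.290% to 0.796%, 4743 UMIs) and 2.97% in dog 2 (2.604% to 3.38%, 4366 UMIs). The low-UMI clusters, as background, gave 0.715% in dog 1 (0.496% to 0.998%, 1189 UMIs) and 2.28% in dog 2 (1.81% to 2.84%, 1904 UMIs). T and NK-like nuclei stood at 2.30% (1.34% to 3.65%, 1512 UMIs) and 3.27% (1.51% to 6.12%, 2062 UMIs). Endothelial-like nuclei stood at 0.784% (0.0951% to 2.80%, 2610 UMIs) and 3.02% (2.13% to 4.14%, 2852 UMIs), and mesenchymal-like nuclei at 1.04% (0.126% to 3.69%, 3134 UMIs) and 2.43% (1.34% to 4.04%, 2676 UMIs). In dog 2 dendritic-like nuclei stood at 6.76% (3.29% to 12.1%, 2155 UMIs). The intervals of macrophage-like nuclei lay above those of the low-UMI clusters in both dogs, as did those of T and NK-like nuclei in dog 1 and dendritic-like nuclei in dog 2. Those of hepatocyte-like, endothelial-like and mesenchymal-like nuclei overlapped the background in both dogs. When at least 3 genes were asked for, macrophage-like nuclei had the highest share in dog 1, at 3.46%, but stood at 1.005% in dog 2, below hepatocyte-like (1.24%), endothelial-like (1.39%), T and NK-like (1.82%) and dendritic-like nuclei (2.70%). The low-UMI clusters then stood at 0.0631% in dog 1 and 0.117% in dog 2, and every named class of dog 2 lay above that. In dog 1 hepatocyte-like nuclei stood at 0.0879%, and endothelial-like and mesenchymal-like nuclei at 0%. The overlap at 2 genes therefore does not show that cycling hepatocyte-like nuclei of dog 2 were background. Unthinned, the shares were 18.1% and 20.9% for macrophage-like, 7.71% and 18.3% for hepatocyte-like and 5.00% and 12.4% for T and NK-like nuclei of dog 1 and dog 2. They were 3.53% and 14.1% for endothelial-like, 8.29% and 16.5% for mesenchymal-like nuclei and 0.904% and 8.48% for the low-UMI clusters.

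**Figure D3:**
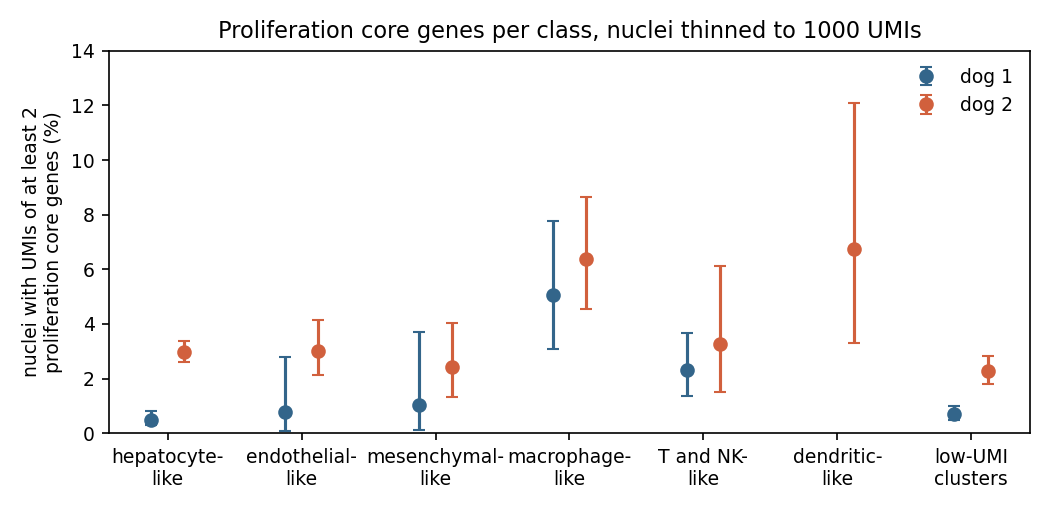
Share of nuclei with UMIs of at least 2 proliferation core genes at 1000 UMIs (percent, vertical axis starting at 0) per class and dog, with 95% exact binomial intervals. Macrophage-like nuclei reached 5.05% and 6.37%, against 0.715% and 2.28% in the low-UMI clusters.

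Ligand and receptor genes were placed by the class with the highest CPM, as a description of level that does not measure signalling. Of 76 pairs, 69 had both genes in the files, 52 were detected in both dogs at 5 CPM or more, and 33 of these had the same leading classes in both dogs. VEGFA led in hepatocyte-like nuclei, at 596.1 CPM in dog 1 and 589.0 in dog 2, and its receptor genes KDR (280.9 and 694.9 CPM) and FLT1 (1285 and 319.5 CPM) in endothelial-like nuclei. HGF led in mesenchymal-like nuclei (658.6 and 555.6 CPM) and MET, its receptor gene, in hepatocyte-like nuclei (250.9 and 333.9 CPM). ANGPT1 led in mesenchymal-like nuclei (676.8 and 563.8 CPM) with TEK in endothelial-like nuclei (839.0 and 874.9 CPM), and IL34 in mesenchymal-like nuclei (199.8 and 156.6 CPM) with CSF1R in macrophage-like nuclei (329.6 and 501.0 CPM). Macrophage-like nuclei led for PDGFC (467.0 and 316.7 CPM), for CD86 (287.8 and 187.7 CPM) and for IL18 (362.5 and 213.6 CPM), whose receptor genes PDGFRA, CD28 and IL18R1 led in mesenchymal-like nuclei for the first of these and in T and NK-like nuclei for the other 2. With the free-RNA background subtracted 55 pairs were detected and 37 had the same leading classes in both dogs, 28 of them the classes found without subtraction.

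Hepatocyte-like nuclei were compared between the dogs without a test, since each dog gave 1 library, so these differences have no replicate check. Of 2129 genes with at least 100 CPM in either dog, 84 were at least 2-fold higher in dog 2 and 87 at least 2-fold lower. Dog 2 expressed SIM1, a transcription factor gene known from the hypothalamus, at 123.5 CPM (95% exact Poisson interval 120.2 to 127.0) against 0.307 in dog 1 (0.123 to 0.632). FSIP1, PRR16, NAV3, ANKRD55, MTUS2 and CCDC141 were also higher in dog 2, by 2.87 to 5.54 (log2). STAB2, a marker of sinusoidal endothelium, was higher by 4.89. With the free-RNA background subtracted, 0 counts of it were left in dog 2 and the ratio turned round. Dog 2 had lower levels of CPS1, the entry enzyme of the urea cycle, at 1745 CPM (1733 to 1758) against 10651 (10609 to 10693), and of the gluconeogenic gene G6PC, at 67.8 (65.3 to 70.3) against 560.6 (551.0 to 570.4). It also had less TAT, which degrades tyrosine, at 297.9 (292.7 to 303.1) against 1699 (1682 to 1716), and less FKBP5, a glucocorticoid-induced gene, at 183.2 (179.1 to 187.3) against 1446 (1430 to 1462). CDH8 (−6.91), MAGI2 (−4.62), SETBP1 (−3.30), ZNF543 (−2.69), CA10 (−2.56), ACTG1 (−2.39) and SLC26A8 (−2.36) were lower as well, and SETBP1 also had 0 counts left in dog 2 after subtraction. The low-UMI clusters differed in the same way, with SIM1 at 1.02 and 170.1 CPM and CPS1 at 11180 and 1632 CPM in dog 1 and dog 2.

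By list, the proliferation core stood apart in hepatocyte-like nuclei, with a median log2 ratio of dog 2 over dog 1 of 2.29 over 13 genes. This lay above the medians of all of 10000 random lists matched on expression, and 11 genes were at least 2-fold higher. It was 2.56 with the background subtracted and 1.29 in the low-UMI clusters. Given with the percentile among such random lists, higher medians were also found for interferon response (0.68, percentile 99.99), G2 and M phase (0.59, 99.99), growth factor ligands (0.49, 99.71), growth factor receptors (0.43, 99.92) and S phase genes (0.32, 96.18). Epithelial-mesenchymal genes stood at 0.44 (98.89), and at 0.12 with the background subtracted. Angiogenic genes had a median of 1.29, above all random lists, which turned negative with the background subtracted, where some members had 0 counts left in dog 2. Lower medians were found for urea cycle and gluconeogenesis (−0.64, percentile 0), bile acid synthesis and transport (−0.62, 0.02) and drug metabolism genes (−0.30, 0.25). Antigen presentation (0.37, 92.09), stem and progenitor (0.27, 90.51), and p53 genes (0.16, 57.86) lay nearer to the random lists, whose medians were between 0.07 and 0.18. So did checkpoint (0.15, 44.22), matrix (0.15, 57.48), lipid (0.14, 67.29), acute phase (0.13, 67.76), Wnt (0.11, 60.04), fatty acid oxidation (0.07, 35.96), chemokine receptor (0.03, 29.3), hypoxia (−0.02, 9.49) and dissociation genes (−0.04, 6.83). Chemokines and cytokines had fewer than 5 members with enough counts and gave no value.

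**Figure D4:**
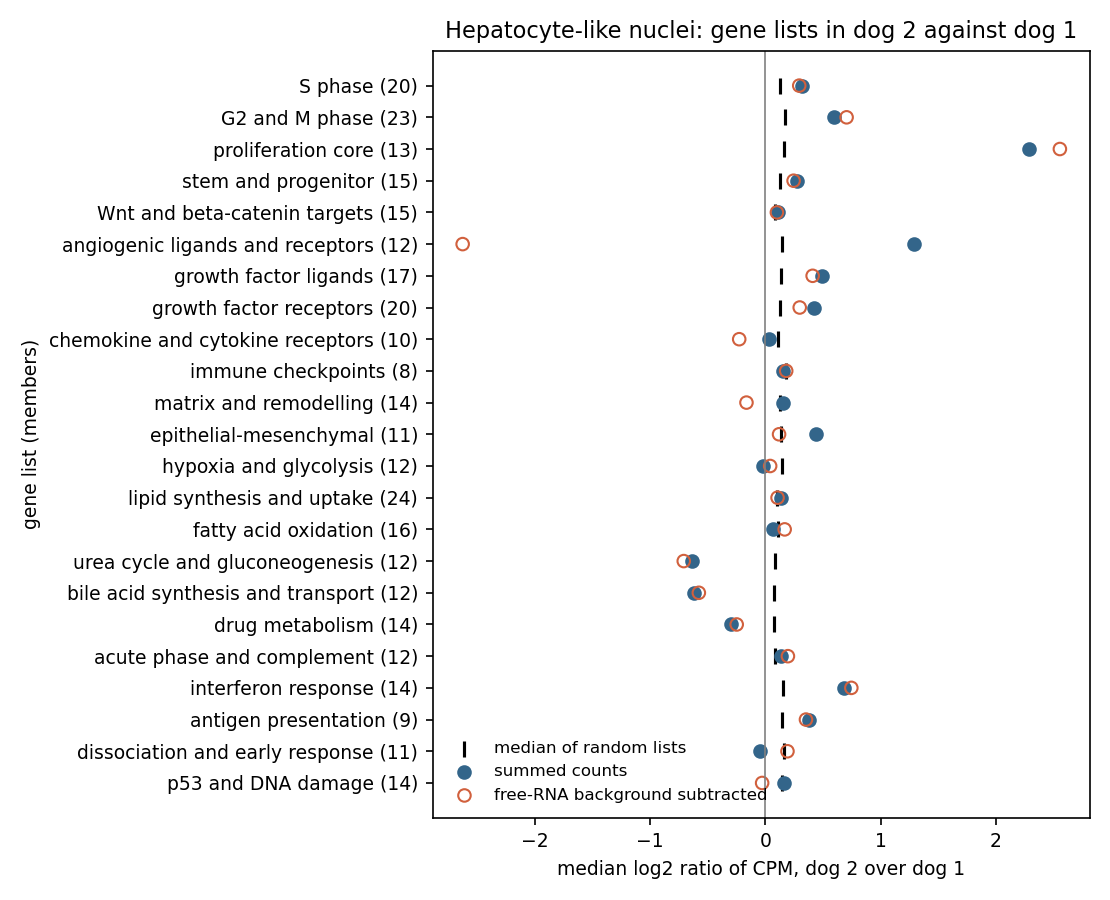
Median log2 ratio of CPM, dog 2 over dog 1, in hepatocyte-like nuclei (horizontal axis) for 23 gene lists (vertical axis), as filled points for summed counts, open points after subtraction of the free-RNA background and dashes for the median of matched random lists. The proliferation core lay at 2.29, and the urea cycle list at −0.64.

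Endothelial-like and macrophage-like nuclei came mostly from clusters with different leading genes in the dogs. Endothelial-like nuclei of dog 1 were mostly a cluster of 223 with VWF, EMCN and PTPRB, and those of dog 2 mostly clusters of 816 with STAB1, STAB2 and CLEC4G and of 410 with BMPER and LDB2. Within this class the laminin gene LAMA4 stood at 217.5 CPM in dog 1 (186.5 to 252.2) and 2.29 in dog 2 (1.10 to 4.21), and BMPER, a regulator of bone morphogenetic proteins, at 29.8 (19.1 to 44.4) and 971.4 (942.4 to 1001). Macrophage-like nuclei of dog 1 were mostly a cluster of 351 with MRC1, CD163 and NLRP1, and those of dog 2 a cluster of 597 with CD5L and MARCO. In dog 2 NLRP1 was among the leading genes of the dendritic-like cluster, so differences in this class may depend on how clusters were named. Within macrophage-like nuclei the factor XIII gene F13A1 stood at 754.8 CPM in dog 1 (707.3 to 804.7) and 6.33 in dog 2 (3.16 to 11.3). In mesenchymal-like nuclei the immediate early matricellular gene CCN1 stood at 576.8 CPM in dog 1 (520.4 to 637.8) and 7.60 in dog 2 (4.04 to 13.0), and FGFR2 at 12.1 (5.23 to 23.9) and 337.1 (310.2 to 365.8). In T and NK-like nuclei the genes that differed most were largely those of the hepatocyte-like nuclei, with CPS1 at 6961 CPM in dog 1 (6811 to 7114) and 1210 in dog 2 (1125 to 1300). Of its 8148 and 751 counts there 96 and 0 were left after subtraction of the free-RNA background.

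Hepatocyte-like nuclei fell into 7 clusters in each dog. In dog 2 a cluster of 141 nuclei (1.86%) was led by CENPF, ASPM, MKI67 and TOP2A, with the proliferation core higher by 4.12 (median log2 over the other hepatocyte-like nuclei), and dog 1 had no cluster led by these genes. A cluster led by ATF3, CREB5, WEE1 and CNTN4 occurred in both, with 119 nuclei (3.49%) in dog 1 and 545 (7.17%) in dog 2. In it urea cycle genes were at −0.90 and −0.65, drug metabolism genes at −0.76 and −0.45, and early response genes at 0.91 and 0.65 in dog 1 and dog 2. Clusters led by HAL, SLC38A4 and GLS2, of 611 nuclei in dog 1 and 1629 in dog 2, had urea cycle genes at 0.28 and 0.25 and Wnt targets at −0.25 and −0.28. Clusters led by RGSL1 and ANK2, of 641 and 2346 nuclei, had Wnt targets at 0.25 and 0.36. Each of the 7 clusters of dog 1 was set against each of the 7 of dog 2 over 5221 genes, and these 3 pairs had correlations across genes of 0.811, 0.657 and 0.672, where genes are not independent replicates. Clusters led by mitochondrial genes held 111 nuclei in dog 1, with a median of 29071 UMIs, and 620 and 55 nuclei in dog 2, with medians of 5107 and 2596 UMIs.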

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

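All tests in this part were chosen after the result was seen. Droplets that the comparisons of named classes left out held a large share of the data. The unnamed low-UMI clusters made up 48.86% of the droplets analysed in dog 1 (exact binomial interval 47.87% to 49.86%) and 24.66% in dog 2 (23.95% to 25.39%). A further unnamed cluster made up 0.2091% in dog 2 (0.1401% to 0.3001%), 29 droplets with a median of 5944 UMIs. It was led by PAPPA, a protease of the insulin-like growth factor system, the receptor kinase gene ALK and the transcription factor gene RUNX2, and it held the bile duct markers PKHD1 and BICC1, fewer than the 3 markers that a name needed.

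The low-UMI clusters may largely be droplets with free RNA. Named classes other than hepatocyte-like carried between 0.787 and 1.05 times as many hepatocyte marker UMIs per droplet as these clusters, as a background shared by all droplets requires. A further cell class in most of them is argued against by 0 genes of 100 CPM or more that lay 2-fold above every named class in both dogs, yet in dog 1 a finer clustering at resolution 2.0 set apart 515 droplets with S100A8 at 76.35 against 14.96 CPM and S100A12 at 67.4 against 8.25 CPM, without counts of CSF3R or CXCR2, so a minor class of neutrophils stays open. Shallow hepatocyte-like nuclei cannot be told apart from free RNA, since markers of the other classes stood at 1.40 times their level in hepatocyte-like nuclei in dog 1 and 1.59 times in dog 2, which passed the bound set against that reading in dog 2 alone. The design gives no groups, so no biological difference between groups was tested.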

How the results depend on the processing

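Over 30 results, 334 values were computed under alternatives, of which 284 stayed near the reported value and 50 moved. Near means a move by less than 1 SD between the dogs for a share, or a count within 1.5 times the reported one. With 2 dogs that SD can be wide, so a share may move far and still count as near. A share with either dog left out always lies within that SD. Those values are counted among the 284 but could not move. Alternatives on UMI totals, low-UMI clusters and free RNA were chosen after the results were seen, and the cause was not tested where none is given. A filter at 500 genes and 1000 UMIs removed no further barcodes, so it says nothing about stability, and its values are also counted among the 284. The share of hepatocyte-like nuclei, 70.8% as a mean of the dogs, was 66.1% without doublet removal, 67.5% at resolution 2.0, 78.7% with barcodes of at least 1.5 times the lowest UMI total and 81.8% with the low-UMI clusters counted as hepatocyte-like. That last choice enlarges the total, so mesenchymal-like nuclei stood at 3.07%, macrophage-like at 4.09%, endothelial-like at 5.74% and T and NK-like at 4.80%. With barcodes of at least 1.5 times the lowest UMI total T and NK-like nuclei, 8.75% ± 8.65 as reported (SD, n = 2), stood at 3.38% and endothelial-like at 7.04%. Mesenchymal-like nuclei stood at 5.88% without doublet removal.

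Cycling shares rose when nuclei were not thinned, because deeper nuclei show more genes, to 13.0% for hepatocyte-like, 8.82% for endothelial-like, 12.4% for mesenchymal-like, 19.5% for macrophage-like and 8.68% for T and NK-like nuclei. Asking for at least 3 genes gave 0.663% for hepatocyte-like, 0.693% for endothelial-like, 0.174% for mesenchymal-like, 2.23% for macrophage-like and 1.04% for T and NK-like nuclei. The macrophage-like share was then 3.46% in dog 1 and 1.005% in dog 2, where every other named class except mesenchymal-like (0.347%) lay above it.

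The pairing of classes within a dog comes from the same animal, and the dog was the block. With no replicate block edgeR called 89 list genes higher and 64 lower in hepatocyte-like nuclei, and the lower ones numbered 2 in endothelial-like, 3 in mesenchymal-like, 10 in macrophage-like and 2 in T and NK-like nuclei. Of 231 named genes 67 were no longer called without the block, and none reversed.

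Against the summed other nuclei, in which the most numerous class weighs most, 161 list genes were lower in hepatocyte-like, 105 higher and 141 lower in endothelial-like, 60 lower in mesenchymal-like, 47 lower in macrophage-like, and 58 higher and 102 lower in T and NK-like nuclei. With the free-RNA background subtracted 33 were lower in hepatocyte-like, 2 in endothelial-like and 3 in mesenchymal-like, while 34 were higher and 7 lower in macrophage-like and 11 lower in T and NK-like nuclei. This ended the calls of 82 of 221 named genes. All 82 kept their sign and 81 had a fold as large or larger, with a median absolute log2 fold of 1.84 before and 3.49 after, while the median SE grew from 0.41 to 1.02. The SE was larger for 77 of them, so the lost calls do not show that these genes were background. With barcodes of at least 1.5 times the lowest UMI total 24 were lower in endothelial-like nuclei. DESeq2 called 23 lower in endothelial-like, 49 in macrophage-like and 18 in T and NK-like nuclei. With no filter on low counts edgeR called 62 lower in endothelial-like and 47 in mesenchymal-like, 107 higher and 83 lower in macrophage-like, and 41 higher and 73 lower in T and NK-like nuclei. Without doublet removal 15 were lower in macrophage-like nuclei. At resolution 0.5 edgeR called 0 lower in T and NK-like nuclei, with 41 at an unadjusted p under 0.05, and DESeq2 was not run there.

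Of 120 list tests camera called 59, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Of the 120 fry called 23, of which 22 were among the 59.

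Between the dogs, a minimum of 20 CPM gave 307 genes higher and 149 lower in dog 2, since it admits more genes. STAB2 reversed to −5.82 (log2) with the free-RNA background subtracted, a value that rests on the prior count because 0 counts were left in dog 2.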

Other observations

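Besides the main types, small clusters of known liver cells appeared in dog 1. A cluster of 32 endothelial-like nuclei carried STAB2 and OIT3, genes of sinusoidal endothelium, beside the larger VWF cluster, and 25 macrophage-like nuclei carried CD5L and MARCO, genes of resident liver macrophages. In dog 2 STAB2 was among the markers of endothelial-like clusters of 816 and 410 nuclei, the latter also with OIT3, and a cluster with CD5L and MARCO held 597. Mesenchymal-like nuclei of dog 1 parted into 119 with COL6A5, PTH1R and COL3A1 and 74 with EDNRB, an endothelin receptor gene, and AKAP6, while the 576 of dog 2 formed a single cluster. Hepatocyte-like nuclei of dog 1 included 321 with the secreted protein genes APOA1 and SAA1 and the ferritin gene FTL, whose top genes also held the B cell gene CD79A.

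The tests in the next paragraphs were chosen after the results were seen, except the glucocorticoid list test, whose bounds were chosen ahead of its result and whose spread was added afterwards. Among the 12 genes listed as lower in hepatocyte-like nuclei of dog 2 were FKBP5, TAT and G6PC, which glucocorticoids induce. With the 50 most abundant genes left out, the median of the listed genes was −2.77 (11 genes). With the background subtracted it was −2.77, against −2.65 before (12 genes). Neither median was smaller in size. The genes were picked for the largest differences, and leaving genes out rescales all ratios alike. The low-UMI clusters also differed in the same way, with G6PC at 532.4 CPM in dog 1 and 77.7 in dog 2. These values therefore do not exclude free RNA. A few abundant genes taking most of the counts in dog 2 would lower its other genes alike. Yet the median log2 ratio of the 2129 genes with at least 100 CPM in either dog was 0.14. Of these 84 were at least 2-fold higher and 87 at least 2-fold lower in dog 2, which argues against that explanation. A different glucocorticoid exposure may be a candidate explanation but cannot be told apart from its absence. The 14 other genes of the glucocorticoid list that reached 5 CPM in either dog had a median of −0.15 in hepatocyte-like nuclei (bootstrap interval −0.54 to 0.27), at percentile 2.08 of random lists. With the background subtracted FKBP5 was also lower in dog 2 in each other class of the fit. It stood at −0.83 in endothelial-like, −3.41 in mesenchymal-like, −1.18 in macrophage-like and −0.72 in T and NK-like nuclei (log2). TAT and G6PC had between 0 and 6 counts left there in dog 2, so of FKBP5, TAT and G6PC only FKBP5 can be compared. Other members of the list went both ways. In endothelial-like nuclei, with the background subtracted, SGK1 stood at 1.33 and SESN1 at 0.56, but PER1 at −1.74 and ZBTB16 at −1.70. Differences between the animals and their treatment stay open as untested.

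A scan of gene order over 5567 genes in 939 windows of 25 genes showed a block of neighbouring genes lower in hepatocyte-like nuclei of dog 2. Its 29 genes run from SRP19 to XRCC4 and include the Wnt pathway gene APC, the glycosylation gene MAN2A1, ELL2 and ARRDC3, with a median of −0.83 and 26 of them below 0. Chance is argued against by 0 of 1000 shuffled gene orders with a window as low as −0.84, and a difference of this size shared by all classes by a median of 0.23 (bootstrap interval 0.03 to 0.34) in the pooled other classes with the background subtracted. Before subtraction, when hepatocyte RNA is included, that median was −0.31 (−0.41 to −0.20), against −0.89 to −0.66 in hepatocyte-like nuclei, and by class the subtracted values lay between −0.20 in T and NK-like and 0.36 in endothelial-like nuclei, so a smaller shared part stays open. A candidate explanation is a copy-number difference in hepatocyte-like nuclei. The median with the background subtracted was −0.95, and clusters of at least 100 nuclei lay within 0.11 of the rest of their dog. The block was picked for its low median, and a lower level with another cause could be as even across clusters. These values therefore do not tell a copy-number difference apart from other causes. Window size and block edges were chosen on the same data, and which dog differs from the normal state was not settled.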
